A study of Mus musculus with 1000 samples.

How the data were processed

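Whole brains without cerebellum were collected from third-generation mice, usually 8 to 12 weeks old, whose male founders had received 3 doses of 100 mg/kg ENU, per the labels' protocols. Total RNA (4 ng) was made into cDNA with a kit that captures the 3' ends of transcripts and amplified for 8 cycles, per the labels' protocols. The cDNAs of a plate row were then pooled, and each pool was made into an indexed library, per the labels' protocols. Elsewhere in this text, a library means a named sample within such a pool. Pools were combined for sequencing as a set of 1152 samples, per the same protocols. This does not place all libraries analysed here in the same set. In such 3' libraries the reads cover the transcript end and would not show the rest of a gene. GSNAP, a read aligner, and the mouse build GRCm38 are named in the submitters' processing notes. The annotation and the counting method are not given in the sources used here, and the expression data themselves were not analysed here.

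The deposited file used was a lookup table of 23231 rows and 3 columns, which hold a running number, a library name and the name of 1 of 3 parts of a data set. Its values were checked, and 0 of the columns after the running number held any numeric value. All 1000 library names of the samples matched a row exactly, and all 1000 were assigned to part 1. The other 22231 rows name libraries outside these samples and were counted but not used otherwise.

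Pedigree, animal, plate and well were read from each library name with Python 3.11.15 and pandas 2.3.3. The labels do not define the parts of the name. The number after "ENU" was taken as the pedigree because 2 labelled groups are named that way, the number after "G3" as the animal, and the number after "neuro" as the plate. No well position occurred more than once on a plate read this way (0 repeats). The number after "S" in the name was not used for grouping. It was shared by rows of different plates whose library names end differently. The libraries may therefore come from different sequencing sets, and no library was assigned to a set here. Groups in the labelled subset followed the submitters' candidate gene or pedigree, key genotype and phenotype labels, and all other libraries were grouped by pedigree.

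Tests of differential expression, a comparison of first and repeat libraries, and a score of inflammation genes per pedigree were planned. Lists of marker genes to be named were set with them. The plan was written with the sample labels already read, so parts of the layout were known by then. None of these was run, because they need expression values. The description of the layout was the only planned result that could be obtained. It was recomputed without the repeat libraries and with pedigrees of at least 6 libraries, and the number of libraries alone was also counted from the lookup table.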

Results

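No gene expression value was analysed here. The only file used was a list of library names that states which part of a larger data set holds each library, and it contained no count, expression level or other measurement. No gene, pathway or cell type could therefore be compared between animals, and the depth of each library is unknown here. The series text places the expression data in another series, which was not used here. The values below describe how the animals, pedigrees and plates were arranged, because that arrangement decides which expression comparisons the design allows.

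The samples were 1000 RNA-seq libraries, each a named sample within a pool, made from mouse brain with the cerebellum removed. The mice descended from C57BL/6NCrl males given N-ethyl-N-nitrosourea (ENU), a chemical mutagen that causes mainly single-base changes, and the mutations were bred towards homozygosity. The stated aim was to find animals with abnormal inflammation in the brain. The libraries came from 988 animals of 87 pedigrees, as read from the library names. With 12 repeat libraries of the same animals counted in, 80 pedigrees had 12 libraries each, so these numbers are not all numbers of animals. The remaining pedigrees had between 2 and 10 libraries among the samples analysed here. Of the 1000 libraries, 36 belonged to a labelled subset, in which some libraries had a genotype or phenotype label. The 964 outside it were grouped by pedigree, and such labels were not counted among them.

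The first question posed by the labels concerns animals with a "Low MG signature", an abbreviation that the labels do not spell out. In the pedigree labelled Nrros C247Y, 3 animals were m/m at the key genotype and carried this phenotype label. Nrros encodes a microglial protein that takes part in the activation of transforming growth factor beta. Another 2 animals of the pedigree had neither a genotype nor a phenotype label. The 3 m/m animals also had the histology block label 1, and these 2 animals had no block label. All 5 stood in row H of plate neuro2001, so a comparison among these animals of 1 pedigree would be made within 1 plate row. A single animal of pedigree ENU43040 carried the same phenotype label, without a genotype, in the same row, and no other animal of that pedigree was among the samples analysed here.

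The second question concerns the label "DAM" in pedigree ENU43055, for which the labels name no gene. The submitters list the pedigree as "ENU43055 original signal", words that the labels used here do not explain. The DAM phenotype label was given to 4 of 6 animals. It was carried by 2 of the 4 m/m animals and by 2 of the 2 m/+ animals. The other 2 m/m animals had no phenotype label, which does not say that they were unaffected. With these numbers the label did not separate the genotypes, and no test was made because a missing label is not a measurement. All 6 animals had the histology block label 2, and all were also in row H of plate neuro2001.

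The 12 animals labelled Unaffected were the remaining libraries of the subset. Like the 2 unlabelled Nrros C247Y animals, these animals had no entry under the genotype, phenotype or histology block label. The labels used here therefore do not state how they were judged unaffected. They all belonged to pedigree ENU53014, and all stood in row H of plate neuro2007. None of the 12 first-run libraries of the other 3 labelled pedigrees was on that plate. In a comparison of either labelled phenotype with the Unaffected animals, the phenotype, the pedigree and the plate therefore cannot be told apart. Comparisons within a pedigree do not have this limit, but they have others. The labels used here do not say how the phenotypes were assigned. If expression in these same libraries was used, a comparison by phenotype label would not be independent of that label. The within-pedigree comparisons also rest on few animals. For Nrros C247Y they set 3 m/m animals against 2 whose genotype and phenotype are not given, so those 2 are not a known unaffected group. For ENU43055 they set 4 animals with the DAM label against 2 without a phenotype label. The 4 were 2 m/m and 2 m/+ animals, whereas the other 2 were m/m, so genotype differs in part between these sides. Among the m/m animals alone, 2 with the DAM label would stand against 2 without a phenotype label.

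Each of the 12 animals of those 3 pedigrees had a second library, labelled as a rerun. The first libraries were on plate neuro2001 and the repeats on plate neuro2020, and all 12 repeats stood in the same well position as the first library. A repeat does not add an animal, and each repeat also differs from the first library in its plate. The labels do not say whether it started from the same RNA. No repeat of an Unaffected animal was among the samples analysed here.

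The 1000 libraries analysed here occupied 85 rows on 16 plates, with 12 to 96 libraries per plate. The lookup table lists 22231 further libraries that were not placed on plates here, so rows and plates may hold libraries that these counts leave out. Among the libraries analysed here, in 82 of the 85 rows all libraries came from 1 pedigree, and 84 of the 87 pedigrees were in a single row. The other 3 were the pedigrees with repeat libraries, and they were in 2 rows only because of the repeats. Their first libraries stood in a single row. The samples of a row were pooled as cDNA before the indexed library of that pool was made, per the labels' protocols. For the pedigrees in rows of 1 pedigree, a difference from other pedigrees would, among these libraries, coincide with a difference between pools. Such a difference may also coincide with a difference between sequencing sets, which was not tested.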

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

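Leaving out the repeat libraries gave 988 libraries, 988 animals, 87 pedigrees and 16 plates. Leaving out pedigrees with fewer than 6 libraries gave 996 libraries, 985 animals, 85 pedigrees and 16 plates. Each setting removed few libraries, so these counts could not have moved far. Without the repeat libraries, 2 of 84 plate rows held several pedigrees, against 3 of 85 with them, and 82 rows held 1 pedigree with or without the repeats. Counted from the lookup table alone, the number of libraries was 23231 instead of 1000, because the table also lists libraries outside these samples. The other settings chosen in advance for expression (normalization, filters, left-out replicates, repeat libraries and permutation within plates) were not run. No paired analysis was possible because no expression values were analysed for the first and repeat libraries of the same animals. Depth could not be assessed.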
